A study of Mus musculus with 24 samples.

How the data were processed

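Expression was measured on 24 single-colour Agilent arrays labelled with Cy3, 2 for each of 12 groups of EpiSC lines, mESC lines and embryonic tissue. According to the submitters' processing notes the scans were read with Agilent Feature Extraction 10.5.1.1. The authors deposited 1 raw file per array, whose processed signal is an intensity on a linear scale, per the file headers. The authors also deposited a table of log2 values scaled to the 75th percentile of each array and centred on each probe's median over all 24 arrays. Each column of these values was matched to its own raw file by correlation (lowest r with its own array 0.99993, highest r with another array 0.793). Array positions fell on 6 slides scanned on 4 days, per the file headers.

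Each array held 62976 spots, of which 3671 were controls, and 55681 distinct probes. Of these, 27235 carried a RefSeq accession found in the annotation and named 20660 genes; 16194 probes to genomic intervals and 10802 others had no gene name and were left out of gene counts. No genome of the array's build was at hand, so no coordinates are given. Values flagged as feature outliers were excluded, which touched 168 probes, and 0 values were saturated. A gene with several probes (5454 genes) was represented by the probe with the highest mean signal over all arrays among those without a flagged value, leaving 20616 genes. The log2 processed signal was scaled by subtracting the 75th percentile of each array.

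The depth of the arrays is given by the share of probes called well above background by Feature Extraction, 36.7% to 53.2%, and 17436 probes were so on every array. Replicate arrays correlated at r of 0.967 to 0.993. A gene entered a fit when it was well above background on both arrays of at least 1 group in that fit. Where no array of a side was well above background, the fold is printed as a bound: on each such array the larger of the gene's own signal and the lowest signal called well above background was used, and the side's mean was set against the mean of the other side. The bound refers to the probe that represents the gene.

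Differential expression was tested with limma 3.58.1 in R 4.3.3, with data read by the package data.table (version 1.17.8). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and at least 2-fold, two-sided, and every adjusted p for a gene is from limma. The 5 EpiSC lines, averaged over their arrays, were compared as 3 lines against 2; the same lines and the 2 mESC lines as 5 against 2; and the 5 line means with the 6 embryo arrays as 4 groups. IWP2 treatment, 2i, the comparisons between stages and the pairs of lines used all 24 arrays as 12 groups. Errors are standard errors of the log2 difference from these fits. The choice of replicate unit, tests and gene lists was made before the data were examined. The labels do not say whether replicate arrays share a culture or a dissection.

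For 26 gene lists, fixed beforehand, called members were counted over all genes and with adjustment over the list alone, and lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. That gave 224 set tests over 9 comparisons, adjusted within each comparison. Genes named in the text were chosen by a rule: in each comparison the 8 largest rises and 8 largest falls among called genes well above background on all arrays of both sides, up to 4 called members of each list described, markers of other cell types whose list was called, and 14 genes given always, called or not. Unnamed, clone and predicted genes were not used for this. Some genes that meet the rule are left out for length, and some are withheld and not reported here.

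The correlations of each line mean with each stage were compared by an exact sign-flip test over the 5 lines and an exact permutation test of 3 against 2 lines. The IWP2 change was compared across genes with the difference between the Wnt inhibitor lines and Wt1. In 20 simulations of noise alone, without a change in any group, the correlation that a shared control produces was obtained. Called gene sets were tested with limma's fry. The fits, the calls, the set tests and the correlation with a shared control were tested on simulated data with known answers and no slide effect. Of 100 genes changed by a log2 of 3, 88% to 100% were called across the 9 comparisons, and of 100 changed by 1.5, 49% to 79%. The other steps were not tested in this way.

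Alternatives covered the background correction, the normalization, the authors' values, the filter on dim probes, the mean of all probes of a gene, a variance model with trend and robust fitting, no fold minimum, fits of only the arrays compared, replicate numbers as a block, lines or slides as a random block, slide as a fixed block, only 1 kind of EpiSC line, rank correlation and leaving out each array and each line. When 1 array or line is left out and a single sample remains on a side, it is assumed to vary like the other groups. The raw files had no mean signal before background subtraction, so the alternative background correction, normexp with offset 50, used the median signal with the median background. Scaling by the 75th percentile of the probes well above background on all arrays was an alternative chosen after seeing the data.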

Results

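Gene expression was measured on 24 single-colour Agilent arrays in mouse stem cell lines and early embryonic tissue, with 2 arrays for each of 12 groups. Epiblast stem cells (EpiSCs) are pluripotent lines taken from the epiblast after implantation, and mouse embryonic stem cells (mESCs) are pluripotent lines taken from the blastocyst. Of 5 EpiSC lines, Wt1 and 129C1 were established by the original protocol, and 129Ba1, 129Ba2 and BNa17 with a Wnt inhibitor. Line 129C1 was also measured after treatment with IWP2, a compound that blocks the enzyme Porcn and with it the secretion of Wnt proteins. The mESC lines were J1 and R1, and J1 was also measured in 2i, which combines inhibitors of Mek and of Gsk3. The tissues were epiblast of E5.5 and E6.5 and embryonic ectoderm of E7.5, dissected by hand. The cell lines were grown on feeder layers and freed from feeders before RNA was prepared. The 75th percentile of the processed signal ranged from 69.3 on BNa17 replicate 1 to 253 on E6.5 replicate 1, and 36.7% to 53.2% of probes were well above background. With 2 arrays per group, their number limits the precision. The labels do not say whether the replicates came from separate cultures or dissections, so the p-values of comparisons between groups of arrays may rest on technical spread only.

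The first comparison asked how lines established with a Wnt inhibitor differed from lines established by the original protocol. Definitive endoderm genes, which mark the precursor of the gut, were lower in the 3 Wnt inhibitor lines than in the 2 original-protocol lines. Of 13 measured, 9 were called lower and none higher. Adjusted over the list alone, 10 were lower and 1 higher, with a median log2 difference of -5.03. Cer1, a secreted antagonist of Nodal and Wnt, was at least 373-fold lower (adjusted p = 0.00455). Such a fold is a lower bound, given where no array of a side was well above background and computed against the lowest signal called so on each array. Foxa2, a transcription factor of endoderm, differed by -8.39 ± 0.31 on the log2 scale (± standard error, adjusted p = 0.00277), with 1 of the 6 Wnt inhibitor arrays well above background. Sox17, another endoderm factor, was at least 25.7-fold lower (adjusted p = 0.00601). Hhex and Gata6 differed by -6.08 ± 0.41 and -5.84 ± 0.41, each with 1 of those 6 arrays well above background. Of 18 primitive streak and mesoderm genes, 3 were lower and 8 adjusted over the list alone. These were the organizer gene Gsc (-6.96 ± 0.22, 2 of 6 arrays well above background), Lhx1 (-4.19 ± 0.26, 5 of 6) and the T-box gene Eomes (-3.92 ± 0.32). Of 17 Wnt target genes, 4 were lower and 5 adjusted over the list alone. Among them the Wnt antagonist Dkk1 was at least 43.4-fold lower and the R-spondin receptor Lgr5 at least 6.53-fold lower (adjusted p = 0.00455 and 0.00522). The set test camera gave adjusted p = 5.59e-11, 1.01e-07 and 1.53e-05 for the endoderm, streak and Wnt target lists, and adjusted p = 0.278 for each with an estimated correlation. Of 7 genes of extraembryonic ectoderm and trophoblast 2 were lower and 3 adjusted over the list alone (camera adjusted p = 4.24e-04, adjusted p = 0.278 with an estimated correlation). The 2 were Ascl2, counted above among the Wnt target genes too, and Tfap2c, also in the list of naive pluripotency. This result is therefore not separate from those lists. Genes higher in the Wnt inhibitor lines included the Wilms tumour gene Wt1, which shares its name with a line (4.27 ± 0.24), the apoptosis gene Pmaip1 (4.90 ± 0.43) and the imprinted noncoding RNA Kcnq1ot1 (at least 2.89-fold). Nme5, of the nucleoside diphosphate kinase family, was lower (-3.88 ± 0.26). T, the brachyury gene, differed by -5.51 ± 0.91, with 1 of 6 Wnt inhibitor arrays well above background, and did not pass (adjusted p = 0.0602). The pluripotency factors Pou5f1, Sox2 and Nanog differed by 0.43 ± 0.26, 0.61 ± 0.18 and -0.15 ± 0.36 and did not pass. Fgf5, Otx2, Klf4, Esrrb, Dnmt3b and Sox1 differed by -1.04 ± 0.53, -0.96 ± 0.44, -0.03 ± 0.65, -1.13 ± 0.47, 1.00 ± 0.35 and 1.43 ± 0.90 and did not pass either, nor did Axin2, dim in the Wnt inhibitor lines on the probe that represents it (another probe at -1.33, adjusted p = 0.219), and Zfp42, dim in the original-protocol lines. In all, limma called 222 of 14038 genes between the line means, 76 higher and 146 lower. With arrays in place of line means as replicates, the 3 Wnt inhibitor lines differed from 129C1, on their slide, at 1689 genes and from Wt1, on another, at 2062. Against 129C1 the endoderm list had a median of -5.09. The count was 40 without line 129Ba2, 42 without BNa17, 87 without 129Ba1, 95 without BNa17 replicate 2 and 635 without 129C1; the endoderm count was 5 without BNa17 replicate 2 and 3 without BNa17, the streak count 10 without 129C1 and the Wnt target count 7 without 129C1 and 2 without 129Ba1, 129Ba2 or BNa17, while Hhex and Gata6 lost their calls without BNa17 (adjusted p = 0.0513 and 0.0552), Sox17 without BNa17 replicate 2 (adjusted p = 0.0816), and Eomes and Pmaip1 without 129Ba2 (adjusted p = 0.0576 and 0.0576) or BNa17 (adjusted p = 0.0552 and 0.0788).

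**Figure D1:**
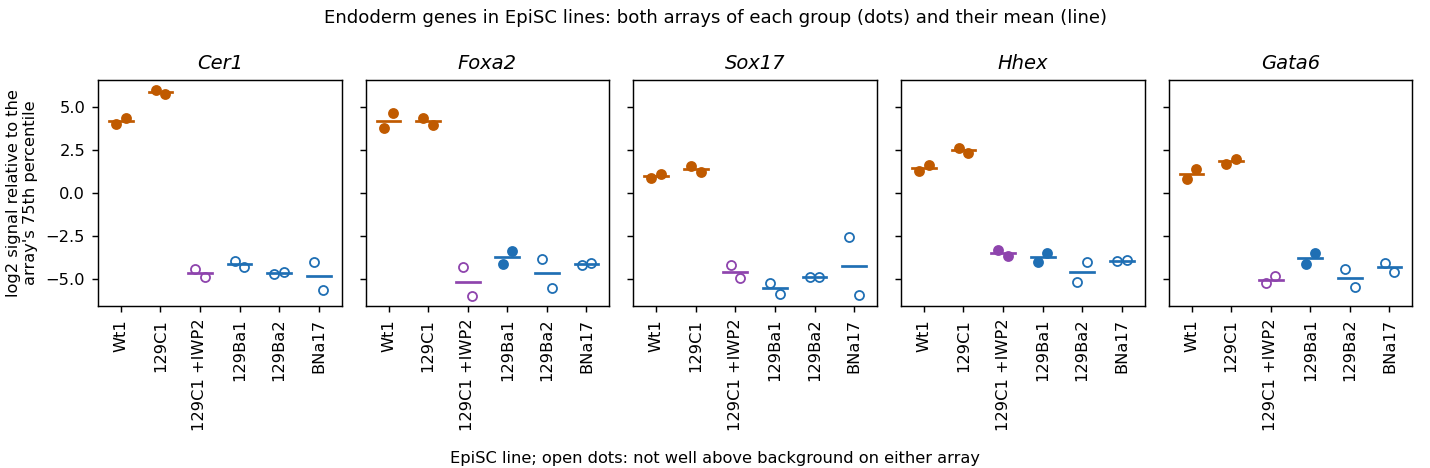
Log2 signal relative to the array's 75th percentile (y axis) of Cer1, Foxa2, Sox17, Hhex and Gata6 in the 6 EpiSC groups (x axis), 1 dot per array with a line at their mean; filled dots belong to groups with at least 1 array well above background, open dots to groups with none. The arrays of Wt1 and untreated 129C1 lie above those of the 3 Wnt inhibitor lines and of IWP2-treated 129C1 for each gene.

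Treatment of 129C1 with IWP2 addressed what blocking Wnt secretion changed in an established original-protocol line (2 treated against 2 untreated arrays). Definitive endoderm genes fell, with 11 of 13 lower over all genes and 11 adjusted over the list alone, and a median log2 change of -5.26. Cer1 was at least 718-fold lower, Foxa2 at least 219-fold, Gata6 at least 43.7-fold and Sox17 at least 31.8-fold (adjusted p = 6.19e-06, 1.00e-06, 2.46e-05 and 6.54e-04). Hhex changed by -5.98 ± 0.50, with 1 of 2 treated arrays well above background. Of 22 streak and mesoderm genes, 8 fell, and 8 adjusted over the list alone. Gsc changed by -6.39 ± 0.45 (1 of 2 treated arrays well above background), Lhx1 by -3.83 ± 0.40, the growth factor Fgf8 by -3.58 ± 0.29 and Eomes by -3.52 ± 0.33. Of 20 Wnt target genes, 6 fell and 2 rose, over all genes and adjusted over the list alone. T was at least 9.61-fold lower (adjusted p = 1.79e-04), Dkk1 at least 32.9-fold, Sp5 at least 11.4-fold and Lgr5 at least 8.55-fold. Among 20 Wnt pathway components, 4 fell and 6 adjusted over the list alone, including the secreted antagonist Sfrp5 (-6.08 ± 0.72), the ligand Wnt3 (at least 5.30-fold) and the receptor Fzd5 (-1.63 ± 0.28). The camera test gave adjusted p = 7.82e-17 for endoderm and 0.00326 for Wnt components, and both were 0.0366 with an estimated correlation. It gave adjusted p = 2.82e-06 for streak genes and 0.0111 for Wnt targets, against adjusted p = 0.0852 and 0.101 with an estimated correlation. The median log2 change was smaller than for endoderm, at -0.74 for streak genes, -0.24 for Wnt targets and -0.36 for Wnt components. Cholesterol synthesis genes had a median change of 0.44, with 0 of 20 called (camera adjusted p = 1.16e-06, adjusted p = 0.166 with an estimated correlation). Of 14 Hox genes, which pattern the body axis, 5 rose and 8 adjusted over the list alone (camera adjusted p = 3.46e-06, adjusted p = 0.166 with an estimated correlation). Hoxa2 was at least 2.67-fold higher. Of 19 neural ectoderm genes 5 rose and 3 fell, the same as adjusted over the list alone (median 0.29, camera adjusted p = 0.0490, adjusted p = 0.131 with an estimated correlation). Sox1 and Fabp7 rose by 2.76 ± 0.26 and 2.20 ± 0.49, while Hesx1 and Rax changed by -5.64 ± 0.40 (1 of 2 treated arrays well above background) and -2.26 ± 0.47. The neural factor Insm1 rose by 3.18 ± 0.18, the gene Wt1 by 3.38 ± 0.26, and Gbx2, a homeobox gene, at least 6.33-fold. The epiblast gene Fgf5 changed by -2.49 ± 0.22, the erythroid factor Gata1 was at least 20.9-fold lower, and Nme5 and the Vegf receptor Flt1 changed by -3.82 ± 0.35 and -4.07 ± 0.32. Pou5f1, Sox2 and Nanog differed by 0.32 ± 0.32, 0.29 ± 0.15 and 0.99 ± 0.31 and did not pass, nor did Klf4 (-1.23 ± 0.50) and Dnmt3b (-0.46 ± 0.23). The probes that represent Axin2 and Zfp42 were well above background on no array of either group, and another Axin2 probe gave 0.30 and was not called (adjusted p = 0.844). With limma, 585 of 15088 genes were called, 210 higher and 375 lower. Treated and untreated arrays lay on different slides, so slide and treatment cannot be told apart for most genes, but the endoderm list was also lower in treated 129C1 than in Wt1 on the same slide (median -4.96), which slide alone would not give. The count of neural genes that fell was 1 without replicate 1 of either group, and Rax then lost its call (adjusted p = 0.0877 treated and 0.104 untreated). Fabp7 lost its call without treated replicate 1 or untreated replicate 2 (adjusted p = 0.139 and 0.150). The Hox count was 2 without treated replicate 1 and 3 without either untreated replicate, Otx2 (-1.04 ± 0.20) lost its call without replicate 1 of either group (adjusted p = 0.0596 treated and 0.0649 untreated), and Esrrb (-1.65 ± 0.46) lost it without any 1 of the 4 arrays (adjusted p from 0.140 to 0.220).

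Whether IWP2 changed 129C1 in the direction of the lines established with a Wnt inhibitor was tested across genes. To share no array, the IWP2 change in 129C1 was set against the difference between the 3 Wnt inhibitor lines and Wt1. Treated 129C1 and Wt1 lay on 1 slide, and untreated 129C1 and the Wnt inhibitor lines on another. A difference between these slides would thus enter with opposite signs and lower the correlation rather than raise it. Over 15088 genes, Pearson's r was 0.366 and Spearman's rho was 0.101. Genes are not independent replicates, so no p is given. The 1099 genes lower in the Wnt inhibitor lines than in Wt1 had a median IWP2 change of -0.42, and 738 of them were lower after IWP2. The 963 genes higher in those lines had a median IWP2 change of 0.18, and 641 of them were higher after IWP2. Limma's fry, a rotation test of whether a set moves 1 way on balance, gave adjusted p = 4.65e-07 for the lower and adjusted p = 0.000756 for the higher set. Of the 375 genes that fell with IWP2, 268 were also lower in the Wnt inhibitor lines than in Wt1, where 27.3 would be shared by chance and 8 were higher. Of the 210 genes that rose, 81 were also higher, where 13.4 would be shared by chance and 17 were lower. With 129C1 as the control of both differences r was 0.621. Simulated noise with a shared control, without a change in any group, gave 0.615. In noise alone only the shared control makes the differences covary, so that r cannot be set against the r of the data. The covariance can be compared, and it was 0.360 in the data and 0.0637 in the simulations. Noise in the shared control thus gave a part of the covariance and not all of it.

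The EpiSC lines were set against the mESC lines to find what separates the pluripotency of the implanted epiblast from that of the blastocyst (5 line means against 2). Genes of naive pluripotency, the state before implantation, were lower in EpiSCs, with 18 of 22 called over all genes, 19 adjusted over the list alone and a median log2 difference of -6.90. The camera test gave adjusted p = 5.99e-11, and adjusted p = 0.0235 with an estimated correlation. Zfp42, also known as Rex1, differed by -10.84 ± 1.03 (2 of 10 EpiSC arrays well above background), Dppa5a by -11.31 ± 0.91 (8 of 10), the nuclear receptor Esrrb by -8.89 ± 0.54 (9 of 10) and Klf4 by -4.90 ± 0.52. Tcl1, a coactivator of Akt, was at least 314-fold lower (adjusted p = 8.93e-06). Of 14 germline genes, 13 were lower, and 13 adjusted over the list alone (median -5.22, camera adjusted p = 5.99e-11, adjusted p = 0.152 with an estimated correlation). The piRNA gene Mael was at least 56.9-fold lower, Prdm14 at least 45.9-fold lower, and Tex19.1 and Rhox5 differed by -7.41 ± 0.29 and -7.85 ± 0.25. Primed epiblast genes went mostly the other way, with 13 of 22 higher and 1 lower, over all genes and adjusted over the list alone (median 1.67, camera adjusted p = 3.02e-04, adjusted p = 0.152 with an estimated correlation). Carbonic anhydrase 14 (Car14) and the neural factor Sox11 were higher by 3.58 ± 0.35 and 2.74 ± 0.35, and the epithelial factor Grhl3 was lower (-3.46 ± 0.53, 9 of 10 EpiSC arrays). Among regulators of DNA methylation, Dnmt3l differed by -8.49 ± 0.42 (8 of 10 EpiSC arrays) and Tet2 by -3.12 ± 0.34. The Nodal pathway gene Lefty1 was higher by 2.25 ± 0.40, the intermediate filament Nes by 2.14 ± 0.15 and the Wnt receptor Fzd2 by 2.50 ± 0.22. Bmp4 and the homeobox gene Cdx1 differed by -3.41 ± 0.47 and -5.33 ± 0.40 (3 of 10 EpiSC arrays for Cdx1). Stress and immediate early genes were lower for 8 of 17, and 8 adjusted over the list alone (median -0.78, camera adjusted p = 0.00583, adjusted p = 0.322 with an estimated correlation). They were led by Fosb (-4.11 ± 0.33, 9 of 10 EpiSC arrays), Egr1 (-3.87 ± 0.47) and Hspb1 (-3.41 ± 0.30). Of 11 genes of extraembryonic ectoderm and trophoblast 6 were lower, the same as adjusted over the list alone (median -2.25, camera adjusted p = 0.0102, adjusted p = 0.425 with an estimated correlation). The X-linked homeobox gene Rhox6 was at least 153-fold lower. Among genes well above background on every array of both sides, the largest rise was the zinc transporter Slc39a8 (5.51 ± 0.60), followed by the sulfotransferase Chst1 (5.16 ± 0.54), and the largest falls included a ribosomal protein S4 gene, Rps4l (-8.01 ± 0.66), and Fbxo15 (-7.51 ± 0.48). Sox2 was lower (-1.85 ± 0.25), Fgf5 and Sox1 were higher (2.33 ± 0.59 and 2.86 ± 0.86), while Pou5f1 (-0.52 ± 0.26), Nanog (-0.51 ± 0.30), Otx2 (0.74 ± 0.50), Dnmt3b (0.14 ± 0.45), T (-3.07 ± 2.02), Axin2 (-2.15 ± 1.04, another probe at 1.02), Sox17 (0.62 ± 2.10) and Foxa2 (-1.22 ± 2.88) did not pass. Nanog rests, here and in the other comparisons, on a probe at a log2 level of -0.91 in J1 and -0.66 in R1. Pou5f1 was at 6.39 and 6.53 there. How well the Nanog probe responds was not tested. Limma called 3615 of 14434 genes, 1862 higher and 1753 lower, and the kinds of line shared no slide or scan day, so slide and kind cannot be told apart for most genes. For naive genes, E7.5 on the slide of J1 had a median log2 level of -1.05, against 4.51 in J1 and -2.40 to -1.53 in the EpiSC lines, which slide alone would not give. J1 and R1, on different slides of 1 scan day, differed at 80 genes. The count was 1945 without line J1 and 2008 without R1, the primed count was 6 without R1, Fgf5 lost its call without J1 or R1 (adjusted p = 0.0610 and 0.155), and Sox1 lost it without Wt1, 129Ba1, 129Ba2, BNa17, J1 or R1 (adjusted p = 0.0607, 0.0616, 0.0693, 0.0521, 0.165 and 0.159).

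**Figure D2:**
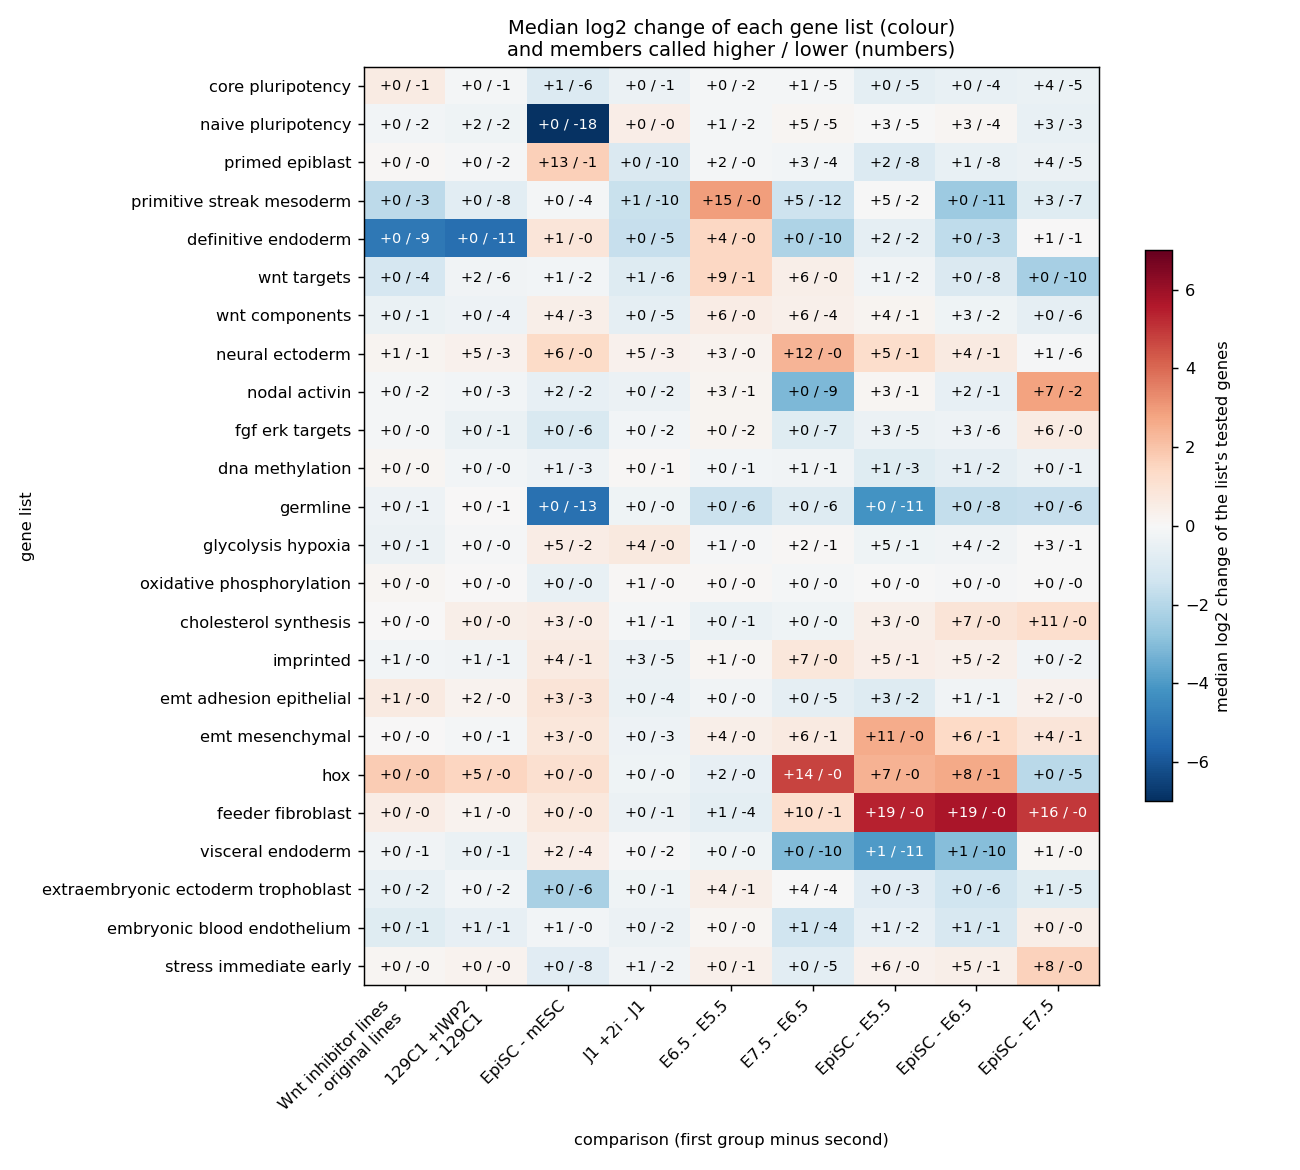
Median log2 difference (colour) of gene lists (y axis) in the 9 comparisons (x axis), for lists tested in all of them; the numbers in each cell are the members called higher and lower. Medians include genes that were not well above background.

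Culture in 2i addressed how inhibition of Mek and Gsk3 changed line J1 (2 arrays in 2i against 2 without). Primed epiblast genes fell in 2i, 10 of 22 over all genes and 10 adjusted over the list alone, with a median log2 change of -1.02 (camera adjusted p = 1.72e-07, adjusted p = 0.0502 with an estimated correlation). Fgf5 changed by -4.62 ± 0.22, the POU factor Pou3f1 by -3.32 ± 0.26, Otx2 by -1.52 ± 0.20, the de novo methyltransferase Dnmt3b by -1.33 ± 0.23 and Fgf15 by -2.54 ± 0.28 (1 of 2 arrays in 2i well above background). Of 22 streak and mesoderm genes, 10 fell and 1 rose, the same as adjusted over the list alone (median -1.54, camera adjusted p = 0.00266, adjusted p = 0.331 with an estimated correlation). T was at least 30.9-fold lower (adjusted p = 3.28e-05), Fgf8 changed by -3.85 ± 0.29 and Gsc by -3.51 ± 0.45 (1 of 2 arrays in 2i). Wnt target genes, which Gsk3 inhibition is known to induce, were lower for 6 of 20 and higher for 1. Adjusted over the list alone, 7 were lower and 1 higher (median -0.90, camera adjusted p = 0.0324, adjusted p = 0.243 with an estimated correlation). Lef1, a transcription factor of the pathway, changed by -1.37 ± 0.24, and the ligands Wnt8a, Wnt5a and Wnt3 were at least 8.92-fold, 6.33-fold and 2.81-fold lower (adjusted p = 4.30e-04, 0.00109 and 1.08e-06). Among 13 endoderm genes 5 fell, the same as adjusted over the list alone (median -1.60, camera adjusted p = 0.00666, adjusted p = 0.410 with an estimated correlation). Cer1 was at least 22.4-fold lower, and Foxa2 changed by -3.89 ± 0.67. The keratins Krt8 and Krt18 changed by -3.04 ± 0.42 and -2.10 ± 0.34, and the splicing regulator Esrp1 by -1.88 ± 0.25. Glycolysis and hypoxia genes rose for 4 of 23, the same as adjusted over the list alone (median 0.67, camera adjusted p = 1.23e-05, adjusted p = 0.366 with an estimated correlation). Bnip3 rose by 1.97 ± 0.26 and Pfkp by 1.21 ± 0.26. The imprinted genes Cdkn1c and Ndn fell (-2.29 ± 0.16 and -1.78 ± 0.21), and Plagl1 and Meg3 rose (2.00 ± 0.36 and 1.78 ± 0.28). Among genes well above background on all 4 arrays, Ndufa4l2, a mitochondrial protein induced by hypoxia, had the largest rise (3.5 ± 0.41), and the secreted kinase Pkdcc the largest fall (-4.88 ± 0.45), followed among others by the neuropeptide Cck (-3.87 ± 0.41), the gene Wt1 (-3.70 ± 0.26) and Amot (-3.64 ± 0.39). None of the 22 naive genes passed over all genes (median 0.48), and before adjustment limma gave 3 higher and 2 lower at the 0.05 level. Nanog, Klf4, Esrrb and Zfp42 differed by 0.86 ± 0.31, 0.71 ± 0.50, 1.09 ± 0.46 and 0.89 ± 0.65 and did not pass, nor did Pou5f1 (-0.40 ± 0.32) or Sox2 (-0.07 ± 0.15). The probes of Axin2 and Sox17 did not give the same answer: the brightest did not pass (Axin2 -0.79 ± 0.48, Sox17 dim in 2i), while another was called at 2.66 for Axin2 and -3.36 for Sox17 (adjusted p = 0.00104 and 0.0117). Limma called 1969 of 15088 genes, 913 higher and 1056 lower, and the 2i arrays lay alone on their slide, so slide and medium cannot be told apart. The endoderm and glycolysis counts were 3 and 2 without 2i replicate 2, and Sox1 (1.1 ± 0.26, another probe at 0.60 not called) lost its call without J1 replicate 2 or 2i replicate 1 (adjusted p = 0.0517 and 0.0674).

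Between E5.5 and E6.5 the epiblast begins to form the primitive streak, and both stages were measured on 1 slide (2 arrays each). Streak and mesoderm genes rose, 15 of 22 over all genes and 18 adjusted over the list alone, with a median log2 change of 2.94 (camera adjusted p = 1.19e-16, adjusted p = 0.00583 with an estimated correlation). Mesp1, a factor of early mesoderm, was at least 307-fold higher (adjusted p = 1.28e-05), T rose by 6.38 ± 0.65 (1 of 2 E5.5 arrays well above background) and the homeobox gene Mixl1 by 5.42 ± 1.01 (1 of 2 E5.5 arrays). The organizer gene Gsc rose by 3.6 ± 0.45, the repressor of E-cadherin Snai1 by 3.74 ± 0.33 and the Nodal antagonist Lefty2 by 3.37 ± 0.62. Wnt target genes rose for 9 of 20 and fell for 1. Adjusted over the list alone, 10 rose and 1 fell (median 1.46, camera adjusted p = 2.17e-05, adjusted p = 0.0114 with an estimated correlation). Sp5 and the feedback inhibitor Nkd1 rose by 5.15 ± 0.52 and 2.58 ± 0.30. Of 20 Wnt components 6 rose, the same as adjusted over the list alone (median 0.49, camera adjusted p = 0.00219, adjusted p = 0.0236 with an estimated correlation). Wnt3, needed for the streak to form, rose by 3.20 ± 0.27. Among 12 mesenchymal genes 4 rose and 5 adjusted over the list alone (median 0.41, camera adjusted p = 8.90e-04, adjusted p = 0.180 with an estimated correlation). Cdh2, or N-cadherin, rose by 1.68 ± 0.23, and Cdh11 and Zeb2 were at least 8.20-fold and 4.26-fold higher. Foxa2 rose by 3.58 ± 0.67 and the Wnt antagonist Frzb at least 19.3-fold, in an endoderm list with 4 of 13 genes up and 5 adjusted over the list alone (median 1.46, camera adjusted p = 2.20e-04, adjusted p = 0.223 with an estimated correlation). Bmp7, the peptide Apln and the neural factor Irx3 rose by 3.95 ± 0.28, 3.5 ± 0.53 and 3.10 ± 0.25. Germline genes fell for 6 of 14 and 8 adjusted over the list alone (median -1.50, camera adjusted p = 8.98e-05, adjusted p = 0.180 with an estimated correlation). Tex19.1 changed by -1.73 ± 0.29 and the meiotic gene Hormad1 by -3.89 ± 0.51 (1 of 2 E6.5 arrays). Single genes that fell included Dppa2 (-4.94 ± 0.63), Dppa4 (-3.59 ± 0.58), Dppa5a (-2.99 ± 0.31), Fgf4 (-2.69 ± 0.29), Gdf3 (-2.66 ± 0.22) and Dnmt3l (-2.85 ± 0.30). Pou5f1, Sox2 and Nanog differed by 0.68 ± 0.32, -0.17 ± 0.15 and -0.73 ± 0.31 and did not pass, nor did Fgf5 (0.58 ± 0.22), Otx2 (-0.17 ± 0.20), Dnmt3b (-0.18 ± 0.23), Sox1 (0.23 ± 0.26), Sox17 (1.06 ± 0.88), Zfp42 (-1.49 ± 0.65), Klf4 (-0.57 ± 0.50) or Esrrb (1.36 ± 0.46). Limma called 734 of 15088 genes, 408 higher and 326 lower, and 412 without E6.5 replicate 1 or 484 without E6.5 replicate 2. The endoderm count was 7 without E5.5 replicate 2 and 2 without either E6.5 replicate, the Wnt component and germline counts were 3 without either E6.5 replicate, and Axin2 (1.82 ± 0.48, another probe at -0.06 not called) lost its call without E5.5 replicate 2, E6.5 replicate 1 or E6.5 replicate 2 (adjusted p = 0.221, 0.196 and 0.0864).

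From E6.5 epiblast to E7.5 embryonic ectoderm (2 arrays each), Hox genes rose, 14 of 14 over all genes and as many adjusted over the list alone, with a median log2 change of 4.72 (camera adjusted p = 2.95e-15, adjusted p = 0.0268 with an estimated correlation). Hoxb2 rose by 5.12 ± 0.43, and Hoxb1 and Hoxb4 at least 39.9-fold and 27.1-fold (adjusted p = 4.45e-09 and 3.05e-05). Their activators Cdx1 and Cdx2 rose by 7.25 ± 0.46 and 5.68 ± 0.94. Neural ectoderm genes rose for 12 of 19, the same as adjusted over the list alone (median 2.38, camera adjusted p = 1.24e-06, adjusted p = 0.00244 with an estimated correlation). The hindbrain boundary gene Gbx2 rose by 6.74 ± 0.42, Lhx5 by 5.09 ± 0.49, Irx3 by 4.51 ± 0.25, the border gene Tfap2a by 5.08 ± 0.64 and the forebrain gene Six3 at least 35.4-fold. Nodal pathway genes fell for 9 of 12, again the same as adjusted over the list alone (median -3.12, camera adjusted p = 1.17e-06, adjusted p = 0.0109 with an estimated correlation). Nodal itself changed by -4.62 ± 0.29, its co-receptor Tdgf1 changed by -6.45 ± 0.87 (1 of 2 E7.5 arrays well above background) and Lefty1 was at least 16.02-fold lower. Streak genes were split, with 12 of 22 lower and 5 higher, the same as adjusted over the list alone (median -1.43, camera adjusted p = 0.0495, adjusted p = 0.322 with an estimated correlation). Mesp1, Eomes and Gsc changed by -5.23 ± 0.92, -4.48 ± 0.33 and -4.07 ± 0.45. Endoderm genes fell for 10 of 13 and 11 adjusted over the list alone (median -2.16, camera adjusted p = 6.67e-05, adjusted p = 0.266 with an estimated correlation). Foxa2 changed by -3.20 ± 0.67, and Cer1 was at least 17.2-fold lower. Visceral endoderm genes, which mark the layer around the epiblast, fell for 10 of 15, the same as adjusted over the list alone (median -3.10, camera adjusted p = 8.45e-06, adjusted p = 0.285 with an estimated correlation). Afp, Apob and Cubn were at least 52.1-fold, 26.3-fold and 24.9-fold lower. The median log2 level of the definitive endoderm list was already -1.03 in E5.5, against 0.73 in E6.5 and -1.96 in E7.5. Whether visceral endoderm in the dissected tissue contributed to its fall was not tested. Fibroblast genes rose for 10 of 19 and fell for 1, and 11 and 1 adjusted over the list alone (median 1.18, camera adjusted p = 4.38e-05, adjusted p = 0.291 with an estimated correlation). Acta2 rose by 2.57 ± 0.45 and the mesenchymal homeobox gene Prrx1 at least 11.3-fold. The primed genes Fgf5 and Pou3f1 changed by -4.35 ± 0.22 and -1.85 ± 0.26, Foxd3 was at least 81.9-fold lower, and Utf1, L1td1 and Dppa5a changed by -2.36 ± 0.22, -2.52 ± 0.22 and -3.90 ± 0.31. Targets of Fgf and Erk signalling fell for 7 of 17, the same as adjusted over the list alone (median -0.83, camera adjusted p = 0.00294, adjusted p = 0.285 with an estimated correlation). The phosphatase Dusp6 changed by -2.97 ± 0.25 and Myc by -2.81 ± 0.33. Sox1 rose by 2.48 ± 0.26 on its brightest probe, while another of its probes gave -1.59 and was also called. Axin2 did not pass on its brightest probe (0.21 ± 0.48), and another was called at 1.29 (adjusted p = 0.0460). For Dnmt3b another probe was called at -1.02. Pou5f1, Sox2 and Dnmt3b moved by less than 2-fold (-0.93 ± 0.32, 0.52 ± 0.15 and -0.88 ± 0.23, adjusted p = 0.0412, 0.0176 and 0.0111), and Nanog (-0.04 ± 0.31), T (0.45 ± 0.65), Otx2 (-0.46 ± 0.20) and Klf4 (0.73 ± 0.50) did not pass. Limma called 2245 of 15088 genes, 953 higher and 1292 lower. The stages lay on different slides, so slide and stage cannot be told apart for most genes. Nodal pathway genes had a median log2 level of 3.17 in E6.5 and -1.31 in E7.5, against 3.80 in J1 on the slide of E7.5. For this list the values argue against slide alone. The endoderm count was 4 without E6.5 replicate 2, the count of fibroblast genes that rose was 4 without either E6.5 replicate and 5 without E7.5 replicate 1, the count of streak genes that rose was 2 without E6.5 replicate 1 and 3 without E6.5 replicate 2, Sox17 (at least 3.03-fold lower) lost its call without E6.5 replicate 2 or E7.5 replicate 2 (adjusted p = 0.117 and 0.0973), Esrrb (-1.91 ± 0.46) without E6.5 replicate 2 (adjusted p = 0.102), and Zfp42 (-1.93 ± 0.65, 1 of 2 E7.5 arrays) without E6.5 replicate 1, E6.5 replicate 2, E7.5 replicate 1 or E7.5 replicate 2 (adjusted p = 0.0964, 0.171, 0.222 and 0.0533).

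The 5 EpiSC lines were next compared with embryonic tissue, first with E5.5 epiblast (5 line means against 2 arrays). Fibroblast genes were higher in the lines, all 19 of 19, over all genes and adjusted over the list alone, with a median log2 difference of 5.38 (camera adjusted p = 5.15e-13, adjusted p = 0.377 with an estimated correlation). Collagens Col1a1 and Col3a1 and smooth muscle actin Acta2 differed by 6.37 ± 0.61, 6.52 ± 0.72 and 6.68 ± 0.50, and Col6a3 by at least 47.2-fold (adjusted p = 9.74e-05). Mesenchymal genes were higher for 11 of 12, the same as adjusted over the list alone (median 2.58, camera adjusted p = 2.93e-06, adjusted p = 0.377 with an estimated correlation). The repressors Zeb1, Snai2 and Zeb2 were at least 19.2-fold, 12.2-fold and 9.19-fold higher. The median log2 level of the mesenchymal list was 1.55 and 1.40 in Wt1 and 129Ba1, against 0.68, 0.44 and 0.34 in 129Ba2, BNa17 and 129C1. That of fibroblast genes was 2.29 and 3.41, against 2.18, 1.17 and 0.78, in the same order. Whether feeder cells left in the RNA contributed to the mesenchymal list was not tested. The calcium binding protein S100a6, osteopontin (Spp1) and the antigen Ly6c1 were higher by 7.64 ± 0.36, 6.82 ± 0.57 and 7.29 ± 0.62. Visceral endoderm genes were lower in the lines for 11 of 15 and higher for 1. Adjusted over the list alone, 12 were lower and 1 higher (median -3.95, camera adjusted p = 2.19e-04, adjusted p = 0.494 with an estimated correlation). Ttr and Apom, carriers of thyroxine and lipids, were at least 39.7-fold and 40.6-fold lower. Germline genes were lower for 11 of 13, the same as adjusted over the list alone (median -4.16, camera adjusted p = 1.70e-09, adjusted p = 0.127 with an estimated correlation). Ddx4, Sycp3 and Mael were at least 33.9-fold, 23.9-fold and 22.6-fold lower, and Tex19.1 and Rhox5 differed by -4.88 ± 0.27 and -4.53 ± 0.47. Core pluripotency genes were lower for 5 of 14, the same as adjusted over the list alone (median -0.66, camera adjusted p = 0.00904, adjusted p = 0.377 with an estimated correlation). They included Dppa2 (-7.12 ± 0.65, 4 of 10 EpiSC arrays well above background), Dppa4 (-6.61 ± 0.32, 1 of 10) and Sall4 (-1.45 ± 0.22). Dnmt3b and Dnmt3l differed by -2.09 ± 0.39 and -7.29 ± 0.37 (8 of 10 EpiSC arrays for Dnmt3l), and Zfp42 and Dppa5a by -4.48 ± 0.93 (2 of 10) and -9.50 ± 0.82 (8 of 10). The Nodal antagonist Lefty1 was higher by 6.92 ± 0.67, the Erk targets Dusp4 and Myc lower (-2.89 ± 0.47 and -2.12 ± 0.32), and Vegfa higher (2.66 ± 0.29). Pou5f1, Sox2, T, Sox17, Foxa2, Fgf5, Klf4 and Esrrb differed by 0.52 ± 0.27, 0.05 ± 0.23, 1.24 ± 1.81, 0.29 ± 1.92, -1.28 ± 2.55, -1.08 ± 0.49, 0.83 ± 0.60 and -1.07 ± 0.61 and did not pass. Limma called 3549 of 14750 genes, 2165 higher and 1384 lower. Tissue and lines lay on different slides, so slide and source cannot be told apart for most genes in this and the next comparisons with tissue. Fibroblast genes were an exception, as they were also higher in J1 than in E7.5 on the same slide (median 3.68). Nodal pathway genes against E7.5 were another. Their median log2 level was 2.87 to 3.74 in the lines and 3.80 in J1, against -1.31 in E7.5. The visceral endoderm count was 7 without E5.5 replicate 2, Nanog (-1.37 ± 0.30) lost its call without E5.5 replicate 2 (adjusted p = 0.0806), Axin2 (-3.11 ± 0.93, 2 of 10 EpiSC arrays, another probe at -0.64 not called) and Sox1 (2.76 ± 0.76, another probe at -0.24 not called) without E5.5 replicate 1 (adjusted p = 0.163 and 0.0938) or replicate 2 (adjusted p = 0.0762 and 0.0986), and Otx2 (-1.20 ± 0.43) without E5.5 replicate 1 or 2, lines Wt1, 129Ba1, 129Ba2 or BNa17, or most single EpiSC arrays (adjusted p from 0.0503 to 0.222).

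Against E6.5 epiblast, fibroblast genes were again higher in the lines, 19 of 19 over all genes and adjusted over the list alone (median log2 difference 5.70, camera adjusted p = 2.56e-15, adjusted p = 0.417 with an estimated correlation; 5 line means against 2 arrays). Col1a1 differed by 7.15 ± 0.61, and Col3a1 and Col6a3 by at least 252-fold and 80.6-fold (adjusted p = 7.82e-05 and 3.92e-05). S100a4, a marker of fibroblasts, differed by 8.19 ± 0.48, the matrix protein Ltbp2 by 6.88 ± 0.73, Cd248 by 6.37 ± 0.50 and the intermediate filament Vim by 3.49 ± 0.28. Streak genes, active in the embryo at this stage, were lower in the lines for 11 of 22. Adjusted over the list alone, 12 were lower and 1 higher (median -2.56, camera adjusted p = 0.00231, adjusted p = 0.417 with an estimated correlation). The lines were not alike: the median log2 level of the streak list was 0.88 in E6.5 and 0.66 in Wt1, against -1.21 in 129C1 and -2.60, -3.11 and -3.02 in 129Ba1, 129Ba2 and BNa17. Mesp1, Evx1 and Mixl1 differed by -9.47 ± 1.46, -7.65 ± 1.20 and -6.34 ± 1.20, with 2 of 10, 2 of 10 and 1 of 10 EpiSC arrays well above background. Wnt target genes were lower for 8 of 20, the same as adjusted over the list alone (median -0.99, camera adjusted p = 0.0159, adjusted p = 0.417 with an estimated correlation). Their median log2 level was 0.97 in E6.5 and 0.77 in Wt1, against -0.60 in 129C1 and -1.99, -2.55 and -2.21 in the 3 Wnt inhibitor lines in the same order. Genes lower in the lines included the feedback inhibitor Axin2 (-4.94 ± 0.93, 2 of 10 EpiSC arrays) and Cdx1 (-3.63 ± 0.36, 3 of 10); another Axin2 probe gave -0.59 and was not called (adjusted p = 0.371). Genes of cholesterol synthesis were higher for 7 of 20, the same as adjusted over the list alone (median 0.90, camera adjusted p = 1.03e-05, adjusted p = 0.417 with an estimated correlation). Msmo1, Dhcr7 and Mvd were higher by 2.09 ± 0.24, 1.53 ± 0.27 and 1.46 ± 0.20. Germline genes were lower for 8 of 13, the same as adjusted over the list alone (median -1.64, camera adjusted p = 1.03e-05, adjusted p = 0.417 with an estimated correlation). Sycp3 and Ddx4 were at least 22.4-fold and 12.03-fold lower, and Dnd1 differed by -4.41 ± 0.26 (9 of 10 EpiSC arrays). Visceral endoderm genes were lower for 10 of 15 and higher for 1, the same as adjusted over the list alone (median -2.99, camera adjusted p = 0.00130, adjusted p = 0.417 with an estimated correlation). Afp, a serum protein of the fetus, was at least 61.8-fold lower. Of 13 genes of extraembryonic ectoderm and trophoblast 6 were lower, the same as adjusted over the list alone (median -1.38, camera adjusted p = 0.00460, adjusted p = 0.417 with an estimated correlation). The placental prolactin gene Prl3d1 differed by -3.98 ± 0.42 (4 of 10 EpiSC arrays). Lefty1, Nes and Tet2 were higher by 5.28 ± 0.67, 2.02 ± 0.16 and 1.81 ± 0.30, and Dnmt3b, Myc and Rhox5 were lower (-1.91 ± 0.39, -2.26 ± 0.32 and -4.42 ± 0.47). Pou5f1, Sox2, Nanog, Sox17, Foxa2, Otx2 and Klf4 differed by -0.16 ± 0.27, 0.22 ± 0.23, -0.64 ± 0.30, -0.77 ± 1.92, -4.87 ± 2.55, -1.04 ± 0.43 and 1.41 ± 0.60 and did not pass. Limma called 3238 of 14750 genes, 1901 higher and 1337 lower, and 1949 or 1966 without E6.5 replicate 1 or 2, with which the streak count was 7 and the Wnt target count 3; the visceral endoderm count was 5 without E6.5 replicate 2 and the Wnt target count 5, 4 and 4 without lines 129Ba1, 129Ba2 and BNa17. Calls were lost without E6.5 replicate 1 or 2 for Fgf5 (-1.66 ± 0.49, adjusted p = 0.151 and 0.116) and Sox1 (2.53 ± 0.76, another probe at -0.56 not called, adjusted p = 0.158 and 0.119), without E6.5 replicate 2 for Esrrb (-2.43 ± 0.61, 9 of 10 EpiSC arrays, adjusted p = 0.141), without E6.5 replicate 1 or 2, 129Ba2 replicate 2 or line 129Ba1 for Zfp42 (-2.99 ± 0.93, 2 of 10 EpiSC arrays, adjusted p from 0.0517 to 0.167), and without E6.5 replicate 1 or 2, lines 129Ba1, 129Ba2 or BNa17, or most single EpiSC arrays for T (-5.14 ± 1.81, 5 of 10 EpiSC arrays, adjusted p from 0.0503 to 0.195).

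Against E7.5 embryonic ectoderm (5 line means against 2 arrays), 16 of 19 fibroblast genes were higher in the lines, the same as adjusted over the list alone (median log2 difference 4.93, camera adjusted p = 6.25e-11, adjusted p = 0.356 with an estimated correlation). Col1a1 and Col6a1 differed by 5.58 ± 0.61 and 5.39 ± 0.59, the antiangiogenic protein Serpinf1 by 5.67 ± 0.51, the actin binding protein Tagln by 5.49 ± 0.52, and the proteoglycan Dcn by at least 125-fold (adjusted p = 3.90e-04). Nodal pathway genes were higher for 7 of 12 and lower for 2. Adjusted over the list alone, 8 were higher and 2 lower (median 2.83, camera adjusted p = 0.00421, adjusted p = 0.356 with an estimated correlation). Nodal differed by 5.26 ± 0.37, its co-receptor Tdgf1 by 6.48 ± 0.95 (1 of 2 E7.5 arrays well above background), and Lefty1 by at least 624-fold. Wnt target genes were lower for 10 of 20, the same as adjusted over the list alone (median -2.34, camera adjusted p = 4.76e-05, adjusted p = 0.356 with an estimated correlation). The median log2 level of this list was 1.63 in E7.5, above Wt1 (0.77) and, further, 129C1 and the Wnt inhibitor lines (-0.60 to -2.55). Among the lower genes were Axin2 (-5.14 ± 0.93, 2 of 10 EpiSC arrays) and Cdx1 (-10.88 ± 0.36, 3 of 10). Another Axin2 probe was also called, at a smaller difference of -1.88 (adjusted p = 0.0189). Hox genes were lower for 5 of 14, the same as adjusted over the list alone (median -1.89, camera adjusted p = 0.00108, adjusted p = 0.487 with an estimated correlation). Hoxb1 and Hoxb8 differed by -5.58 ± 1.05 and -3.36 ± 0.46 (2 of 10 and 1 of 10 EpiSC arrays), and their activator Cdx2 was at least 208-fold lower. Against E6.5, 8 of the 14 Hox genes were higher and 1 lower (median 2.66), and against E5.5, 7 were higher and 0 lower (median 2.43). Camera gave adjusted p = 0.00460 and 0.0128, and 0.454 and 0.670 with an estimated correlation. The lines were not alike. The median log2 level of the Hox list was -1.44 in BNa17, -2.18 in Wt1, -2.30 in 129Ba1, -2.84 in 129Ba2 and -5.36 in 129C1. It was -5.22 in E5.5, -5.42 in E6.5 and -1.34 in E7.5. Cholesterol synthesis genes were higher for 11 of 20, the same as adjusted over the list alone (median 1.18, camera adjusted p = 4.12e-07, adjusted p = 0.356 with an estimated correlation). Msmo1 was higher by 2.54 ± 0.24 and Hmgcs1 by 1.59 ± 0.22. Stress genes were higher for 8 of 17 and 11 adjusted over the list alone (median 1.64, camera adjusted p = 0.00108, adjusted p = 0.356 with an estimated correlation). The Erk target Egr1 was at least 18.4-fold higher. The regional genes Irx3, Tfap2a and Six3 were lower (-3.81 ± 0.66, -5.39 ± 0.49 and -4.14 ± 0.60; 7 of 10 and 7 of 10 EpiSC arrays for Tfap2a and Six3), as were the receptor Ror2 (-3.67 ± 0.23) and Wnt6 (-6.28 ± 0.77, 2 of 10). Foxd3, a repressor expressed in epiblast, was at least 23.9-fold higher, L1td1 differed by 2.34 ± 0.26, the cell cycle inhibitor Cdkn2a by 5.33 ± 0.42, Stat3 by 3.06 ± 0.44 and Spp1 by at least 253-fold. Pou5f1, Sox2, Nanog, Foxa2, Otx2, Zfp42, Klf4, Esrrb, Dnmt3b and Sox1 differed by 0.77 ± 0.27, -0.30 ± 0.23, -0.59 ± 0.30, -1.66 ± 2.55, -0.58 ± 0.43, -1.06 ± 0.93, 0.67 ± 0.60, -0.52 ± 0.61, -1.03 ± 0.39 and 0.06 ± 0.76, and they and Sox17, dim in E7.5, did not pass. Limma called 2591 of 14750 genes, 1683 higher and 908 lower, and 1546 without E7.5 replicate 1, with which the stress count was 2 and the cholesterol count 7. The stress count was 4 without E7.5 replicate 2 and the Wnt target count 6 without either E7.5 replicate, Fgf5 (2.69 ± 0.49) lost its call without E7.5 replicate 1 (adjusted p = 0.0505), and T (-5.59 ± 1.81, 5 of 10 EpiSC arrays) lost it without either E7.5 replicate, Wt1 replicate 2, 129C1 replicate 2 or lines 129Ba1, 129Ba2 or BNa17 (adjusted p from 0.0525 to 0.248).

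**Figure D3:**
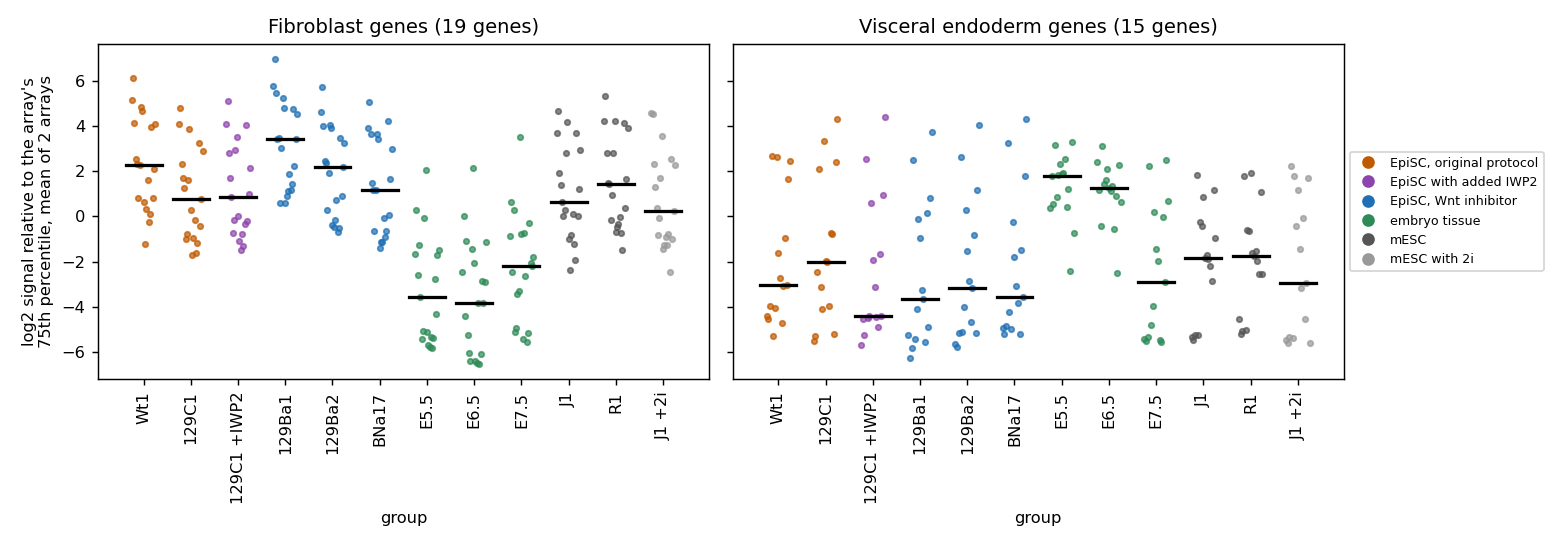
Log2 signal relative to the array's 75th percentile (y axis) of 19 fibroblast and 15 visceral endoderm genes in the 12 groups (x axis), 1 dot per gene as the mean of 2 arrays; black lines are medians. The cultured groups lie above the tissues for fibroblast genes, and E5.5 and E6.5 above the others for visceral endoderm genes.

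How closely the EpiSC lines resembled each stage was measured by Pearson's correlation over 15088 genes. The mean r of the 5 lines was 0.908 with E5.5, 0.916 with E6.5 and 0.925 with E7.5 (standard deviations 0.0135, 0.0121 and 0.00947). Each line correlated more with E7.5 than with E6.5, by 0.00919 on average, and more with E6.5 than with E5.5, by 0.00818, while E7.5 exceeded E5.5 by 0.0174. Markers of other cell types differed between the stages too, and their part in this order was not tested. The median log2 level of visceral endoderm genes was 1.78, 1.24 and -2.88 in E5.5, E6.5 and E7.5 and -3.66 to -1.99 in the lines. That of fibroblast genes was -3.56, -3.81 and -2.21 in the stages and 0.78 to 3.41 in the lines. The exact two-sided sign-flip p was 0.0625 for each of the 3 differences, the smallest that 5 lines allow, and adjusted for the family of 3 it stayed at 0.0625. All 5 lines were set against the same 2 arrays of each stage. This p therefore measures the spread between lines and not between embryo samples or slides. Over the 1000 genes with the largest range over the stage means, the mean r was 0.401, 0.546 and 0.599, but there 129C1 correlated more with E6.5 (0.635) than with E7.5 (0.551). In contrast, the mESC line J1 correlated most with E5.5 over those genes, with r of 0.695, 0.551 and 0.325. Over all 15088 genes J1 had r of 0.913, 0.896 and 0.885. With E5.5 it thus lay within the range of the EpiSC lines (0.889 to 0.920), so a high r over all genes is not particular to EpiSCs. The 3 Wnt inhibitor lines and the 2 original-protocol lines showed no difference that passed (differences 0.00987, 0.00418 and 0.00927, exact two-sided permutation p = 0.5, 0.7 and 0.3, smallest possible 0.1, adjusted p = 0.7 for each).

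**Figure D4:**
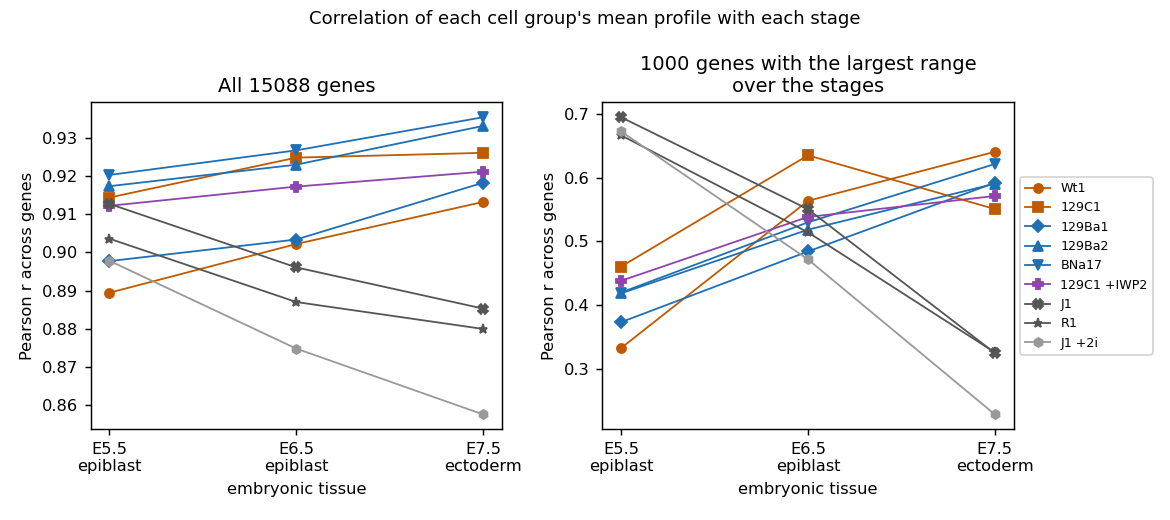
Pearson's r (y axis) of each cultured group's mean profile with the 3 tissue stages (x axis), a line joining the values of each group, over all 15088 genes and over the 1000 genes with the largest range over the stages.

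The lines were also compared with each other, 1 pair at a time (10 pairs, 2 arrays per line). Limma called a median of 1636.5 genes per pair. Among the 3 Wnt inhibitor lines the counts were 98 for 129Ba2 with BNa17, 180 for 129Ba1 with 129Ba2 and 1046 for 129Ba1 with BNa17. The last pair was also the furthest apart in fibroblast genes, whose median log2 level was 3.41 in 129Ba1, 2.18 in 129Ba2 and 1.17 in BNa17. Wt1 and 129C1, both from the original protocol, differed at 1594 genes. Pairs of a Wnt inhibitor line with an original-protocol line differed at a median of 2094 genes, from 1234 to 2363. On the slide that 129C1 shared with the Wnt inhibitor lines these pairs had a median of 1679, and pairs with Wt1, on another slide, had a median of 2186.

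**Figure D5:**
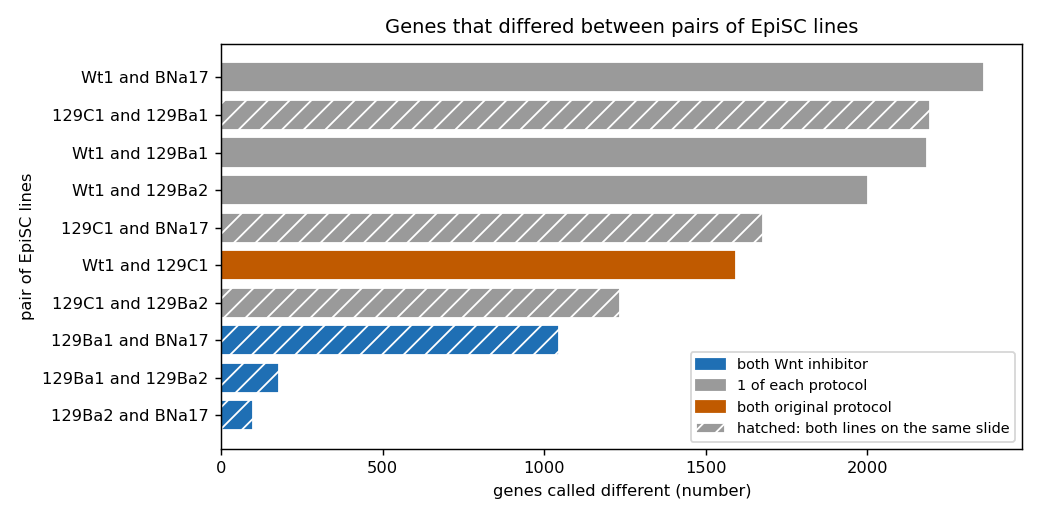
Number of genes called (x axis) between each pair of the 5 EpiSC lines (y axis); bar colours give the protocols of the pair and hatching marks pairs on the same slide.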

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

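The tests below were chosen after seeing the result they address, apart from the counts over all ways of splitting the lines, which were planned. Definitive endoderm genes were lower in the 3 Wnt inhibitor lines than in the 2 original-protocol lines, and slide, sex, a dim array or Wnt inhibition could each account for it. Within the slide of 129C1 and the Wnt inhibitor lines the median of the 13 genes was -5.09 (limma's fry, adjusted p = 6.26e-07), and between IWP2-treated 129C1 and Wt1, which shared a slide, it was -4.96 (adjusted p = 1.95e-06); 129Ba2, which like the original lines expressed Xist, gave -4.28 against them (adjusted p = 8.26e-07), and without BNa17 it was -5.01 (adjusted p = 4.57e-07), all of which argue against slide, sex and the dim array. IWP2 on 129C1 gave -5.26 (adjusted p = 8.26e-07, over the 7 fry tests of this section), as Wnt inhibition would produce. The fry tests of this section took arrays as replicates, so their p-values do not measure the spread between lines. The value set against sex rests on 1 line, 129Ba2. The observed split of the 5 lines was the 1 of 10 with as many genes called, 222 against 2 for the next, but 10 splits are too few for a share under 0.05. Every other split also puts lines of both protocols on at least 1 side. Their difference then enters the spread and few calls are forced, so these counts decide nothing.

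Fibroblast genes were higher in the cultured lines than in embryonic tissue, which could come from slide or from feeder cells left in the RNA, although the labels say the stem cells were separated from their feeders. J1 and E7.5 shared a slide, and there the median of the 19 genes was 3.68 (limma's fry, adjusted p = 8.26e-07), which argues against slide. Of the 19 genes 16 were above all 6 embryo arrays in each of the 5 EpiSC lines, as feeder RNA would give; the threshold for this was set after the value was seen, and expression by the cultured cells themselves was not tested. Of these genes 13 were well above background in embryonic tissue and 11 in E7.5, all 19 were in EpiSC and in mESC lines, and none was in another list.

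Visceral endoderm genes were higher in E5.5 and E6.5 than in E7.5 tissue, which could come from visceral endoderm left on the dissected tissue or from slide. Of the 15 genes 13 were lower in E7.5 than in both earlier stages, as remnants of that layer would give, with a threshold set after the value was seen. The median was -3.10 between slides (limma's fry, adjusted p = 0.000337), and as no slide held E7.5 with an earlier stage, slide and tissue cannot be told apart. All 15 genes were well above background in embryonic tissue, 7 in E7.5, 10 in EpiSC lines and 10 in mESC lines, and none was in another list.

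The split of the 7 lines into EpiSC and mESC was the 1 of 21 with as many genes called, 3615 against 61 for the next. Every other split puts an mESC line with EpiSC lines, so their difference enters the spread and few calls are forced. The kinds of line also shared no slide or scan day, so these counts do not decide what separates them. BNa17 replicate 1 had a 75th percentile of 69.258, against 166.9 to 210.2 for the other 5 arrays of its class. It also had 36.707% of probes well above background, against 45.8% to 49.4%; 25 sets of values were examined in this way and 2 stood out, where chance flags about 1 in 20 groups, or 1.25. Of 9737 tested probes without a gene name, 2189 were called between EpiSC and mESC lines, 1236 higher and 953 lower, and they were not analysed further. Of the genes of the extraembryonic ectoderm and trophoblast list, 13 of 14 were well above background in embryonic tissue, 8 in E7.5, 7 in EpiSC and 10 in mESC lines, and 6 were in another list.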

How the results depend on the processing

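Most values held under the alternatives, and the cause was not tested where one changed, unless stated. Normexp on the median signal called fewer genes: 273 for IWP2, 1959 for EpiSC against mESC lines, 613 for 2i, 300.0 for E6.5 against E5.5, 866 for E7.5 against E6.5, 1675, 1749 and 1290.0 for the lines against E5.5, E6.5 and E7.5, and 725 as the median of line pairs. Requiring every array to be well above background, which tests fewer genes, gave 77 for the Wnt inhibitor lines, and 216, 2159, 910.0, 289, 883, 1864, 1625, 1346 and 730.0 in the same order. Without the fold minimum, which can only add genes, the counts were 3960.0 for 2i, 1346 and 4145 for E6.5 against E5.5 and E7.5 against E6.5, 5736, 5450.0 and 4245 for the lines against tissue, and 3008 for pairs. For the Wnt inhibitor lines against the original lines (222), the count was 135 without the filter, 726 with line as a random block, 637 with a replicate block added, 1689 for 129C1 alone on 1 slide with arrays as replicates (2062 for Wt1 alone, on another slide, in the same fit) and 402 with the mESC lines as another class. A replicate block gave 572, 1981, 722 and 2235 for IWP2, 2i, E6.5 against E5.5 and E7.5 against E6.5; residuals of the same replicate number correlated at 0.101, 0.0108, 0.221 and 0.0200, where 66 pairs of groups ranged from -0.246 to 0.221 and E6.5 with E5.5 was the highest. Fitting only the arrays of E6.5 and E5.5 gave 488. Leaving out 1 array or line gave 40.0 (129Ba2) to 635 (129C1) for the Wnt inhibitor lines, 1945 (J1) to 3716 (Wt1) for EpiSC against mESC, 412 (E6.5 replicate 1) to 797 (E5.5 replicate 1) for E6.5 against E5.5, 1949 (E6.5 replicate 1) to 3314 (Wt1) and 1546 (E7.5 replicate 1) to 2738 (Wt1) for the lines against E6.5 and E7.5. Scaling to detected probes moved the median of all genes by more than 0.1 in log2: from 0.07 to -0.04 for the Wnt inhibitor lines, -0.01 to 0.26 for EpiSC against mESC (0.10 with quantile normalization), -0.07 to 0.07 for E7.5 against E6.5, -0.04 to 0.09 against E5.5 and -0.10 to 0.11 against E6.5. With it the share of called genes that were higher went from 51.5% to 68.5% for EpiSC against mESC (38.3% with normexp), 46.4% to 57.2% for 2i (35.3% with quantile normalization), 42.4% to 53.6% for E7.5 against E6.5 and 58.7% to 72.6% against E6.5.

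The correlations of the lines with E5.5, E6.5 and E7.5 were 0.943, 0.948 and 0.95 with normexp, 0.946, 0.952 and 0.954 without the filter, and 0.401, 0.546 and 0.599 over the 1000 genes with the largest range; with every array well above background they were 0.922, 0.931 and 0.934. With the authors' values they were -0.318, -0.272 and -0.134, reversed because centring each probe removes the differences in level between genes. The correlation of the IWP2 change was 0.330 with normexp, 0.311 without the filter, 0.251 with every array well above background, 0.621 with 129C1 as a shared control, 0.101 by rank, and 0.284 (Wt1 replicate 2) to 0.374 (Wt1 replicate 1) leaving out 1 array. Of 84 lists past the camera test 9 held with an estimated correlation and 41 with every array well above background; the germline median from E6.5 to E7.5 went from -0.90 to 0.03 with normexp. Zic1 in 2i reversed to -0.13 with the mean of its probes, and Zscan4c in the lines against E6.5 to 0.000367 with normexp and 0.14 with the mean of its probes. Another probe was called in the opposite direction for at most 18 of the genes called in a comparison (2i).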

Other observations

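All tests here were chosen after seeing the data. Lines differed in the genes that tell the sex of their cells. Xist, the RNA that silences an X chromosome, was at 0.27 and 0.41 on the log2 scale in Wt1 and 129C1 and at -1.13 in 129Ba2, and not well above background in 129Ba1 and BNa17 (2 arrays each). Eif2s3y, on the Y chromosome, was at 2.74 and 3.12 in 129Ba1 and BNa17, at -4.37 in Wt1 (1 of 2 arrays well above background), and not well above background in 129Ba2 and 129C1. Ddx3y, also on the Y chromosome, was at 1.52 and 1.41 in 129Ba1 and BNa17 and at -3.97 and -3.33 in Wt1 and 129Ba2 (1 of 2 arrays each), and not well above background in 129C1. The imprinted RNA Kcnq1ot1 was at -2.03, -2.18 and -1.94 in the Wnt inhibitor lines and not well above background in Wt1 and 129C1. Cdkn1c, an imprinted gene of the same cluster, was at 4.17, 3.76 and 4.66 in 129Ba1, 129Ba2 and BNa17, -0.84 in Wt1 and 3.54 in 129C1.

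IWP2-treated 129C1 still differed from the lines established with a Wnt inhibitor at 1405 genes (limma, 596 higher and 809 lower; 2 arrays against 6), but they lay on different slides, so slide is mixed with line and treatment. Pmaip1, an apoptosis gene, differed by -5.13 ± 0.22, the opioid peptide gene Penk by -4.87 ± 0.23 and the sterol sensor Insig1 by -4.74 ± 0.19. Of the 19 fibroblast genes 10 were lower (median -1.17, camera adjusted p = 0.000609, adjusted p = 0.802 with an estimated correlation). Between the mESC lines, R1 and J1 also on different slides, differed at 80 genes (limma, 38 higher and 42 lower in R1). Gsc differed by -2.63 ± 0.45, and Cer1 and Lhx1 were at least 16.6-fold and 4.2-fold lower in R1. Fibroblast genes tended to be higher in R1, though none of 19 was called (median 0.47, camera adjusted p = 0.00922, adjusted p = 0.770 with an estimated correlation).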
